A study of Zea mays with 12 samples.

How the data were processed

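The samples were endosperms of 4 maize genotypes, the inbreds B73 and Mo17 and their reciprocal hybrids, harvested 19 days after pollination from field-grown plants. Per the labels' protocols, crosses were made on 3 dates, those of 1 replicate within 30 minutes of each other, and 6 endosperms from each of 6 ears were pooled, giving 36 endosperms per sample. Replicates are thus separate pools of separate crosses, and p-values measure the spread between such pools from 3 dates in a single season. Total RNA (8 micrograms) was labelled with biotin by a one-cycle method and hybridised to Affymetrix maize arrays of a single colour, 1 array per sample, 12 in all.

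The values analysed are the deposited intensity values, 1 signal per probe set and array on a linear scale, which the authors made with MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and its detection calls are not given in the sources used here. The deposited trimmed means (2% at each end) ran from 304 to 458 between arrays, so the arrays were not at a common value, and the first replicates of both inbreds were dimmest. The main analysis kept the values as deposited, and the direction of calls is given again after each of 3 scalings. No scan dates or batches other than the crossing dates were given.

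Of 17734 probe sets, 113 Affymetrix controls were left out, and of the other 17621 the dimmest 33.3% by mean over the 12 arrays were left out, which left 11748. Values were analysed as log2(signal + 10.6), the constant being the 20th percentile of all deposited values. Folds on that scale understate the change of dim probe sets. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) in a fit of all 4 genotypes with 8 residual degrees of freedom, 19.9 with the prior. The Benjamini-Hochberg method adjusted p over the probe sets tested, with a threshold of 0.05, and all tests were two-sided.

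Non-additive expression was a hybrid's mean log2 level minus log2 of the parents' mean on the linear scale, weighted 2 parts female to 1 part male (0.667 and 0.333). Standard errors came from the delta method with limma's moderated variance. Departure from dose was the reciprocal difference minus its expectation under the same weights, signed toward the female or male parent and tested over the 5013 probe sets whose inbreds differed. The female was taken to be the parent written first. Positions and weights of the parents were medians over probe sets with an inbred difference of at least 2-fold, computed for each replicate number.

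Gene names came from the platform's annotation, updated through the current NCBI gene table, with a synonym where the symbol was only a locus number. Of 17734 probe sets, 1452 had 1 gene, 1 had several and 16281 had none in the annotation, and 857 tested probe sets had a named gene, so most results concern unnamed probe sets. Probe sets whose names end in s_at or x_at can bind transcripts of related genes, so levels within families such as the zeins, the glutathione transferases and the meg and bap genes are uncertain. Before the data were examined, a rule was set for the named genes: per comparison, the 8 highest and 8 lowest changes among called probe sets with 1 named gene that moved the same way in all 3 same-numbered sets of arrays, 1 probe set per gene, plus the 2 members of each gene list with the smallest p among those called. For zeins, starch and sucrose use, literature imprinted genes, embryo markers and green tissue markers the 2 were named whether called or not, and at most 2 unnamed probe sets were named per direction. Other list members are named here as examples, chosen after their values were seen.

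The 20 gene lists were also set beforehand, by symbol and by title pattern. The annotation held no usable titles, so members of families were matched by symbol or synonym once the annotation could be read and before gene values were looked at, and 5 genes that only share a symbol with a listed gene were left out. Lists with at least 4 tested genes were tested with limma's cameraPR at a preset correlation of 0.01, and again with a correlation estimated from the residuals, 1 probe set per gene, adjusted over the lists of a comparison. Of 10 calls with the preset value, 2 held with an estimated correlation. In the lists that passed, median, mean and test had the same sign.

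Replicate numbers mark shared crossing dates, per the labels, and so pair the samples across genotypes. Deviations from the genotype means correlated at 0.0486 to 0.409 between arrays of the same number (18 pairs, 13 of them over 0.1) and at -0.323 to 0.168 between arrays of different numbers (36 pairs). The main fit had no block, and the block was run as an alternative.

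Each step was tested on simulated data with 200 probe sets changed by known folds. Changes of 2-fold were recovered at 80.6% for the inbred difference, 82.1% for the reciprocal difference, 98.5% and 92.5% for non-additive expression in B73xMo17 and Mo17xB73 (each over 11748 probe sets), and 80.6% for departures from dose (over 5559). Changes of 1.5-fold were recovered at 20.9%, 28.4%, 37.3%, 31.3% and 19.4% in the same order. Unchanged probe sets called in these runs numbered 5, 5, 9, 15 and 9. The noise was drawn independently for each probe set and array, without deviations shared by arrays of a crossing date.

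Alternatives set before the data were examined were no added constant and a constant of 41.9 (the 40th percentile), no filter and the dimmer 50% left out, quantile normalization and median centring, the replicate block, a fit of only the groups compared, eBayes without the trend, an adjusted p under 0.10, a change of at least 1.5-fold, an expectation on the log2 scale, equal weights, and each array left out in turn. Scaling to the trimmed mean, the alternatives for positions and weights, and the tests of technical explanations were added after the data had been seen. Detection calls, probe-level data and genome coordinates were not used here.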

Results

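Transcript levels were measured in maize endosperm, the triploid storage tissue of the kernel, 19 days after pollination. The samples came from the inbred lines B73 and Mo17 and from their reciprocal hybrids, B73xMo17 and Mo17xB73. Endosperm holds 2 maternal genome doses and 1 paternal dose, so the reciprocal hybrids carry the same alleles in opposite proportions. The parent written first was taken as the female by convention, which the labels do not state. Each of the 4 genotypes had 3 biological replicates, and each replicate was a pool of 36 endosperms on an array of its own, giving 12 arrays. The number of arrays limits the precision, with a median standard error of 0.197 on the log2 scale for a difference between genotypes. Across probe sets, which are not independent of one another, arrays of the same genotype correlated at 0.979 to 0.992 and arrays of B73 with arrays of Mo17 at 0.87 to 0.881. The arrays were not equally bright. The trimmed mean signal was 397 ± 81.5 in Mo17, 336 ± 30.5 in B73, 392 ± 21 in Mo17xB73 and 348 ± 7.26 in B73xMo17 (SD, n = 3). Median shifts are given for the inbreds, for the reciprocal hybrids and for each hybrid against its male parent.

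The inbred lines were compared first, because their difference sets what can be seen in the hybrids. B73 endosperm had a far higher signal for dzs18, a sulfur-rich delta zein storage protein, at 15200 ± 889 against 45.2 ± 31.4 in Mo17 (SD, n = 3). Signals for o2, which encodes the opaque2 activator of zein genes, were also higher, at 3540 ± 502 against 190 ± 28.2. So were those for ohp1, which encodes a partner of opaque2, with a log2 difference of 1.55. Mo17 endosperm had higher signals for zSSIIa, a starch synthase, at 3220 ± 799 against 324 ± 156. The same held for mn1, the cell wall invertase that splits incoming sucrose, at 273 ± 93.6 against 40.9 ± 22.3. Signals compare transcript levels only where probes match both lines equally well, which was not tested gene by gene. In all, 5013 of 11748 probe sets tested with limma differed at an adjusted p under 0.05, and 2032 of these differed at least 2-fold. Of the 5013, 1574 (31.4%) were higher in B73 and 3439 (68.6%) in Mo17. That split depended on the scaling of the arrays: the median shift over all tested probe sets was -0.21, and 47.6% were higher in B73 after quantile normalization, 43.5% after median centring and 49.0% after trimmed mean scaling.

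Among the named genes with the largest inbred differences, the log2 difference of dzs18 was 8.23 (SE 0.24, adjusted p = 8.77e-16). Over the alternative settings this probe set gave 7.51 to 8.66, whereas another probe set of dzs18 gave 4.65 to 5.35. On the B73 side followed MRP2 at 5.18, HRGP, a cell wall glycoprotein, at 4.54, o2 at 4.15 (SE 0.21, adjusted p = 1.87e-12), the tubulin gene tub6 at 3.74, the histone gene his2b5 at 3.44 and GTPase and PLTP at 3.41 each. PLTP was uneven between B73 arrays, at 790 ± 677. On the Mo17 side, pdc2 had the largest difference at -6.61 (SE 0.239, adjusted p = 1.43e-14), followed by CAF1 at -3.84, UMPS at -3.78, the ribosomal protein gene rpl39 at -3.65 and zSSIIa at -3.35 (SE 0.299, adjusted p = 1.43e-08). Next came opr1, an oxophytodienoate reductase gene by name, at -3.34, fdh1 at -2.94 and aos1, an allene oxide synthase gene, at -2.76. The probe sets of pdc2 did not behave alike: a brighter one gave 961 in B73 and 1040 in Mo17 and was not called (adjusted p = 0.924). Those of rpl39 also differed over the alternative settings, at -3.84 to -3.43 for the one above and -1.48 to -1.08 for another. Signals under the added constant of 10.6, such as that of pdc2 in B73 (4.97 ± 3.1), make these folds too small. Among probe sets without a named gene, Zm.15394.1.S1_at at 7.93 and Zm.15876.1.A1_at at 7.52 were highest in B73, and Zm.14705.1.S1_at at -8.56 and Zm.17686.1.A1_at at -7.44 were highest in Mo17.

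The fixed gene lists placed these differences in the tissue. Of 8 markers of the basal transfer cell layer, which takes up nutrients from the mother plant, 6 were higher in Mo17, with bap1-b, an antifungal protein of the basal layer, at 1090 ± 347 against 165 ± 18.8 and meg2 at 3020 ± 994 against 573 ± 81.5 (adjusted p = 0.0065 for the list, and adjusted p = 0.645 with an estimated correlation). Of 8 zeins, 2 were higher in B73, dzs18 and the alpha zein z1C1_12, the second at 5780 ± 901 against 3690 ± 910, although its call was lost without Mo17 replicate 2 (adjusted p = 0.0836). The zein list had an adjusted p of 0.0406, an adjusted p of 0.645 with an estimated correlation, and an adjusted p of 0.36 after quantile normalization. Of 6 endosperm transcription factors, 2 were higher in B73, o2 and ohp1, with the same adjusted p of 0.0406, an adjusted p of 0.645 with an estimated correlation and an adjusted p of 0.105 after quantile normalization. PBF, the prolamin-box binding factor, stood at 3480 in B73 and 4240 in Mo17 and was not called.

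No other list passed its test between the inbreds. In starch and sucrose use, 2 of 20 genes were higher in B73 and 7 in Mo17, with sh2 and bt2, the subunits of ADP-glucose pyrophosphorylase, close to equal at 13400 against 13000 and 7100 against 7750. Of 7 genes of amino acid metabolism, 1 was higher in B73 (lkrsdh1, 368 ± 55.2 against 221 ± 15.1) and 3 in Mo17, among them gln2, a glutamine synthetase, at 245 ± 50.4 against 112 ± 23.2, and lkrsdh1 was lost without B73 replicate 1 (adjusted p = 0.0536). Of 15 genes of ER chaperones and protein folding, 6 were higher in Mo17, with the disulfide isomerase pdi4 at 464 ± 107 against 133 ± 35.8. Of 21 genes of oxidative stress and detoxification, 3 were higher in B73 and 10 in Mo17, with the glutathione transferases gst2 at 172 ± 44.7 against 31.2 ± 8.72 and gst31 at 820 ± 40.3 against 225 ± 23.6. In central carbon metabolism 1 of 17 was higher in B73 (pep4) and 6 in Mo17 (pep7 among them), and in chromatin and DNA methylation 2 of 26 and 4 of 26, the latter with sdg110 and set105. Heat shock proteins gave 4 and 2 of 7, with hsp22 higher in Mo17 at 738 ± 396 against 150 ± 35.1. Histones gave 1 and 2 of 5, cell cycle and DNA replication genes 2 and 3 of 9 with pcna2, a replication clamp, higher in Mo17, and ribosomal proteins 3 and 3 of 20. Aleurone markers gave 1 and 2 of 6 and housekeeping genes 0 and 1 of 4, the latter elfa3, which was lost without Mo17 replicate 2 (adjusted p = 0.0531), after trimmed mean scaling (adjusted p = 0.0543) and with only the groups compared (adjusted p = 0.058). Embryo markers gave 1 and 3 of 4, with the embryo globulin glb1 at 480 ± 225 in Mo17 against 97.1 ± 51.2. Of 8 genes described as imprinted in the literature, 2 were higher in B73 and 1 in Mo17. One of these was mez1, a Polycomb gene, at 1050 ± 49.8 in B73 against 759 ± 110 (adjusted p = 0.0356), whose call was lost without B73 replicate 1 (adjusted p = 0.0652), 2 (0.123) or 3 (0.0718), without Mo17 replicate 1 (0.0533) and with only the groups compared (0.101). The list test compares a list with all other probe sets, and its direction differed in sign from the list's median or mean for heat shock proteins, aleurone markers, literature imprinted genes and ribosomal proteins. Counts adjusted over the list alone were the same, except for heat shock proteins (4 and 3), literature imprinted genes (0 and 1) and ribosomal proteins (3 and 2). The lists of green and maternal tissue markers and of defence and inhibitors had 3 tested genes each, under the 4 required for a list test, and no transposon gene was named on the array. Of these, the photosystem gene psah1 (62.7 ± 8.78 against 31.2 ± 4.55) and the proteinase inhibitor psei2 were higher in B73, psei1 was higher in Mo17 at 4190 ± 771 against 1810 ± 279, and lhcb6 was not called (adjusted p = 0.24).

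The reciprocal hybrids were then compared with each other, since they carry the same alleles in opposite doses and differ in which line was the mother plant. Higher in Mo17xB73 were 7 of 8 transfer cell markers, zSSIIa, sus1 and mn1. The signal of zSSIIa was 3380 ± 851 in Mo17xB73 and 372 ± 147 in B73xMo17, sus1, a sucrose synthase, had 1790 ± 160 against 394 ± 290, and mn1 had 296 ± 71.6 against 67.9 ± 34.7 (SD, n = 3), so that in each hybrid the level lay near that of its female parent. On the other side, HRGP was higher in B73xMo17 at 681 ± 218 against 107 ± 18.2 and GRF5 at 362 ± 49.4 against 71 ± 18.5. In all, 1353 of 11748 probe sets differed, 356 (26.3%) higher in B73xMo17 and 997 (73.7%) higher in Mo17xB73. This split too depended on the scaling, with a median shift of -0.14: 53.1% were higher in B73xMo17 after quantile normalization, 51.9% after median centring and 53.9% after trimmed mean scaling. The inbreds also differed at 1094 of the 1353, with the same sign at 1060 and the opposite sign at 34, while at 259 no inbred difference was called. The count was 2075 with the replicate number as a block, 2137 with only the groups compared, 2514 after quantile normalization and 2326 after trimmed mean scaling. It fell to 732 without Mo17xB73 replicate 3, to 757 without B73xMo17 replicate 3 and to 860 without B73xMo17 replicate 2, and 29 of 38 named calls were kept without either replicate 3.

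**Figure D1:**
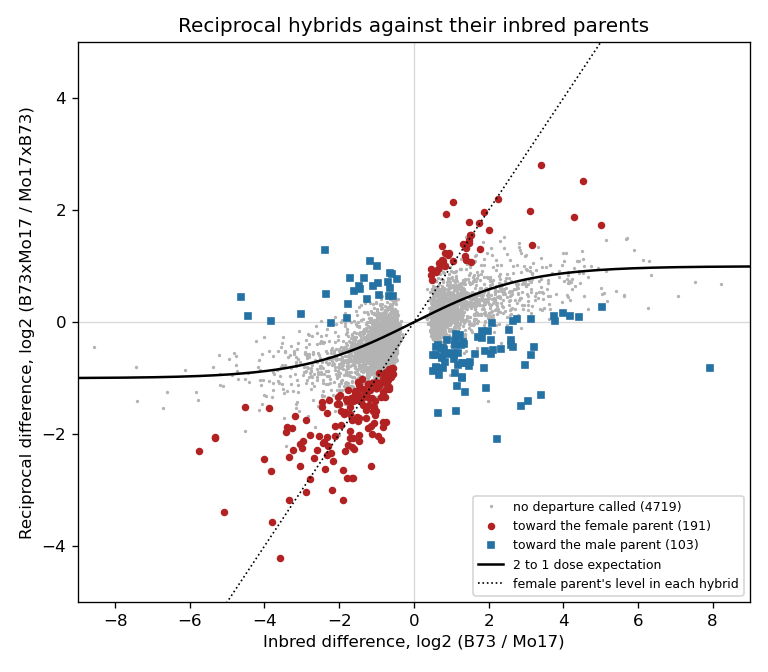
Log2 difference between the reciprocal hybrids (vertical axis, B73xMo17 over Mo17xB73) against the log2 difference between the inbreds (horizontal axis, B73 over Mo17) for the 5013 probe sets whose inbreds differed, 1 point each. The solid curve is the expectation of 2 maternal doses to 1 paternal dose and the dotted line the level of the female parent in each hybrid; the 191 probe sets that departed toward the female parent lie beyond the curve and the 103 that departed toward the male parent lie on its other side.

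Among named genes, the log2 reciprocal difference was -3.17 for zSSIIa (SE 0.299, adjusted p = 1.19e-06), -2.41 for opr1, -2.37 for sus1 (SE 0.364, adjusted p = 0.000243), -2.27 for the cell wall enzyme gene xet1 and -2.21 for the peroxiredoxin gene per-1. The xet1 signal in Mo17xB73 was uneven, at 259 ± 273. Higher in B73xMo17 were HRGP at 2.51 (SE 0.229, adjusted p = 1.02e-06), GRF5 at 2.21, sig3 at 1.65, aba1 at 1.39, GTPase at 1.15, SnrK1 at 1.1 and the auxin-binding protein gene abp1 at 1.02. The pyruvate decarboxylase genes pdc1 and pdc3 were higher in Mo17xB73, the first at 4050 ± 860 against 1710 ± 276 and the second at 1360 ± 149 against 652 ± 92.1, as were the glutathione transferases gst2 at -1.86 and gst5 at -1.85 and the glutamine synthetase gene gln2 at -1.81. The alpha zein z1C1_12 was higher in Mo17xB73 at 7220 ± 1540 against 3710 ± 602, the reverse of its inbred difference. The opaque2 gene o2 was higher in B73xMo17 at 2780 ± 343 against 1760 ± 566 (adjusted p = 0.0338), a call lost without Mo17xB73 replicate 2 (adjusted p = 0.187) or 3 (0.0964) and without B73xMo17 replicate 1 (0.11) or 3 (0.111). Without a named gene, Zm.18395.1.S1_at at 2.81 and Zm.16299.2.A1_a_at at 2.15 were highest in B73xMo17, and Zm.5754.1.A1_at at -4.21 and Zm.13013.1.A1_at at -3.58 were highest in Mo17xB73.

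Transfer cell layer markers were the list that stood apart between the reciprocal hybrids. Of 8 markers, 7 were higher in Mo17xB73, and all 8 when adjusted over the list alone, with the replicate block or after quantile normalization. The signal of meg2 was 3880 ± 339 in Mo17xB73 and 949 ± 250 in B73xMo17, that of bap2 1520 ± 276 against 340 ± 80.2, that of bap1-b 1230 ± 140 against 253 ± 75.3 and that of BET1 2190 ± 289 against 813 ± 268. Further markers were betl4 at 394 ± 107 against 107 ± 23.7, bap-1a at 517 ± 105 against 115 ± 28.2 and betl3 at 373 ± 58.4 against 166 ± 12.6. The smallest difference was that of meg6, 996 ± 6.05 against 666 ± 152, which was not called over all probe sets (adjusted p = 0.054) but was called with the replicate block and after quantile normalization. The list had a median log2 difference of -1.91, an adjusted p of 1.23e-16 and an adjusted p of 0.00211 with an estimated correlation. Every Mo17xB73 array lay above every B73xMo17 array for 8 of 8 markers. Chance gives 5% in this direction only for equally bright arrays. Here every Mo17xB73 array was the brighter, with trimmed means of 377 to 416.1 against 339.8 to 353.1. The markers' residuals were also correlated (estimated at 0.629), so the 8 are not independent. In the same arrays, the embryo markers glb1 (594 ± 92.3 against 141 ± 135, adjusted p = 0.00169) and ole1 (1230 ± 296 against 563 ± 467, adjusted p = 0.0243) were also higher in Mo17xB73. The call of ole1 was lost after quantile normalization (adjusted p = 0.0577) and trimmed mean scaling (0.0541), without B73xMo17 replicate 2 (0.123) or 3 (0.144) and without Mo17xB73 replicate 2 (0.0806) or 3 (0.103). The embryo list had 2 of 4 members lower in B73xMo17 and none higher, 3 lower and 1 higher when adjusted over the list alone, and did not pass its test (adjusted p = 0.409). Neither psah1 (adjusted p = 0.305) nor lhcb6 (adjusted p = 0.499) differed between the hybrids. No other list passed, the lowest adjusted p among them being 0.225, for oxidative stress and detoxification. Starch and sucrose use had 1 of 20 genes higher and 3 lower in B73xMo17 (adjusted p = 0.616, and adjusted p = 0.901 with an estimated correlation).

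**Figure D2:**
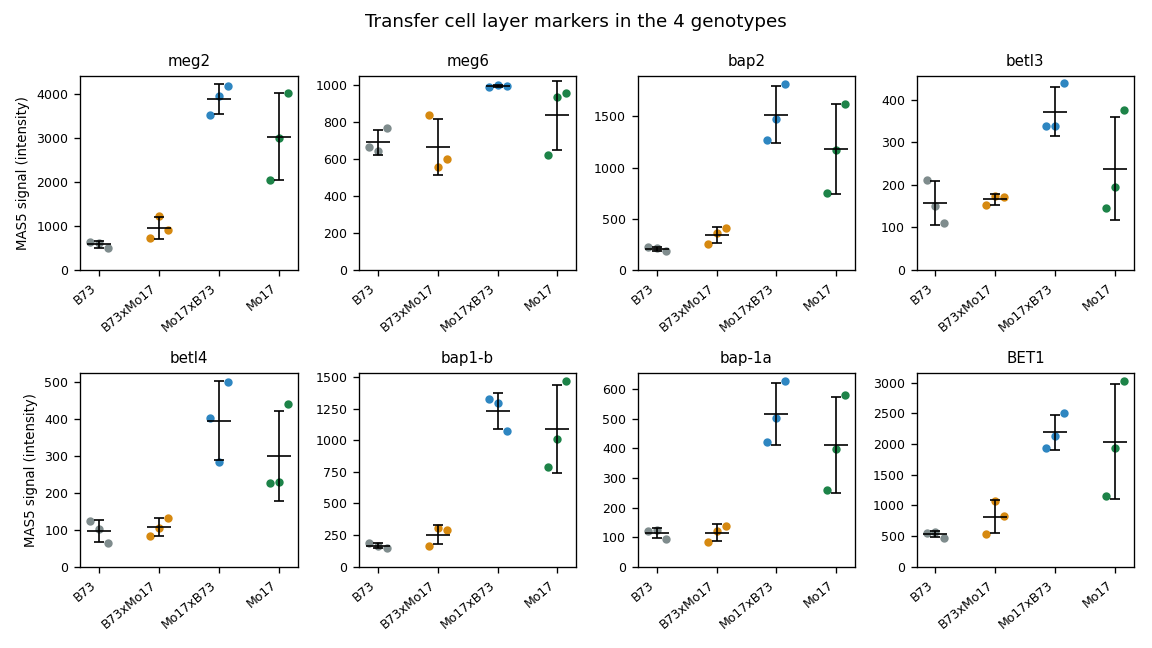
MAS5 signal (intensity, linear axes starting at 0) of the 8 transfer cell layer markers in the 4 genotypes, with 1 point per array, the mean as a horizontal bar and 1 SD as whiskers (n = 3). The Mo17xB73 points lie above the B73xMo17 points in each panel, from 3880 against 949 for meg2 to 996 against 666 for meg6.

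To place the hybrids between their parents, each hybrid's position was expressed as a fraction from the Mo17 level (0) to the B73 level (1), on the linear scale, as the median over the 2032 probe sets whose inbreds differed at least 2-fold. B73xMo17 lay at 0.728 ± 0.0567 and Mo17xB73 at 0.346 ± 0.0919 (SD, n = 3), against 0.667 and 0.333 for a dose of 2 to 1. The weight of the female parent, from the difference between the hybrids, was 0.684 ± 0.0238, within its spread of 0.667. Across the 5013 probe sets with an inbred difference, the slope of the reciprocal on the inbred log2 difference was 0.277, against 0.259 for the dose expectation. The correlation across these probe sets was 0.699 (Pearson) and 0.736 (Spearman), and probe sets are not independent replicates.

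Departures from that dose expectation, which the series title calls imprinted expression, were sought among the same 5013 probe sets. Starch synthase zSSIIa departed most toward the female parent among named genes, at 2.36 on the log2 scale (SE 0.301, adjusted p = 5.66e-05), followed by hmt1 at 1.83, sus1 at 1.72 (SE 0.371, adjusted p = 0.00732), glb1 at 1.71, opr1 at 1.60, HRGP at 1.60 (SE 0.23, adjusted p = 0.000192), bap1-b at 1.57 and per-1 at 1.57. Toward the male parent departed PLTP at -2.17 (SE 0.553, adjusted p = 0.0231), z1C1_12 at -1.16 (SE 0.203, adjusted p = 0.00109), acco20 at -1.07, calmodulin at -1.02, an1, a gene of gibberellin synthesis, at -0.93, UGlcAE at -0.89, CAF1 at -0.88 and tub6 at -0.73. In all, 294 of 5013 probe sets departed, 191 (65.0%) toward the female and 103 (35.0%) toward the male parent. With an expectation on the log2 scale, 334 departed and the majority turned, 157 (47.0%) toward the female and 177 toward the male parent. The median weight of the female parent was 1.13 among the 191 (upper quartile 1.37) and 0.239 among the 103. These probe sets were picked for departing, which favours extreme weights. A weight of 1 is the female parent's level in each hybrid, so above 1 the hybrids differed by more than the inbreds did. For CAF1 the hybrids were level, at 188 ± 41.8 in B73xMo17 and 183 ± 26.7 in Mo17xB73, with parents at 22.4 ± 5.89 and 458 ± 56.3. Among the 103, 34 had a called reciprocal difference opposite in sign to the inbred difference, z1C1_12 and an1 among them. Without a named gene, Zm.5754.1.A1_at at 3.38 and Zm.13013.1.A1_at at 2.72 departed most toward the female parent, and Zm.15004.1.S1_at at -2.71 and Zm.2207.1.A1_at at -2.25 toward the male parent.

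Of 6 transfer cell layer markers with an inbred difference, 5 departed toward the female parent and all 6 did when adjusted over the list alone, under the replicate block or after quantile normalization. Among them were bap-1a at 1.56 (SE 0.252) and meg2 at 1.39 (SE 0.227). The list had an adjusted p of 4.8e-12, and an adjusted p of 0.0103 with an estimated correlation. Of 9 genes of starch and sucrose use, 3 departed toward the female parent (zSSIIa, sus1 and mn1), also when adjusted over the list alone. This list had an adjusted p of 0.0164, an adjusted p of 0.503 with an estimated correlation, and an adjusted p of 0.227 after quantile normalization. Outside these lists, gln2 departed by 1.47, gst5 by 1.49, gst2 by 1.25, pdi4 by 0.99, pdc3 by 0.79 and pdc1 by 0.76, all toward the female parent. No other list passed with the arrays as deposited (lowest adjusted p = 0.197, for embryo markers). The list of genes described as imprinted in the literature had too few members with an inbred difference for a test there. After quantile normalization 3 of 5 departed toward the female parent, with a median of 0.49 (adjusted p = 0.0118, and adjusted p = 0.0683 with an estimated correlation). Of these genes, meg2 passed and mez1 did not at 0.44 (SE 0.185, adjusted p = 0.216), although mez1 passed after quantile normalization (adjusted p = 0.019), median centring (adjusted p = 0.0158) and trimmed mean scaling (adjusted p = 0.0194). The count of departures was 466 with the replicate block, 559 after quantile normalization and 454 after trimmed mean scaling, and it fell to 140 without B73xMo17 replicate 3, 154 without Mo17xB73 replicate 3 and 181 without B73xMo17 replicate 2. With each array left out in turn, zSSIIa, opr1, HRGP, bap1-b, bap-1a, meg2, gln2, gst2, gst5 and CAF1 passed each time. Of 29 named departures, 17 were kept without B73xMo17 replicate 3, where adjusted p rose to 0.0556 for sus1, 0.19 for glb1, 0.197 for per-1, 0.128 for PLTP, 0.247 for UGlcAE, 0.13 for tub6, 0.0677 for pdi4 and 0.106 for pdc3. Adjusted p was 0.144 for calmodulin without Mo17xB73 replicate 3, and 0.0679 for acco20 and 0.181 for pdc1 without Mo17xB73 replicate 1. The inbred difference of z1C1_12, an1 and hmt1 was not called without Mo17 replicate 2, so that their departures were not tested there, and an1 was not tested after any of the 3 scalings. Over all alternatives, the departure of UGlcAE was kept in 6 of 20, that of per-1 in 10 of 21, those of glb1, an1 and pdc1 in 11 of 21, that of PLTP in 13 of 21 and those of hmt1, calmodulin, tub6 and pdc3 in 17 of 21. After quantile normalization, PLTP (adjusted p = 0.0676), glb1 (0.0528) and per-1 (0.0677) were not called.

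Non-additive expression was tested as each hybrid's distance from the dose-weighted mean of its parents. In B73xMo17, GRF5 (362 ± 49.4) and the bZIP factor gene obf3.2 (299 ± 105) lay above both parents, the latter with parents at 122 ± 6.79 and 163 ± 56.3, as did an1 at 260 ± 34 with parents at 135 ± 3.69 and 191 ± 27.9. Below expectation were zSSIIa at 372 ± 147 and opr1 at 109 ± 13.1, both near the level of B73 alone. The log2 distance was 1.04 for obf3.2 (SE 0.221, adjusted p = 0.0269), 1.03 for GRF5 and 0.72 for an1. It was -1.79 for zSSIIa (SE 0.277, adjusted p = 0.00198), -1.76 for opr1, -1.25 for bap1-b, -1.21 for pdi4, -1.18 for hmt1, -0.83 for gst2, -0.81 for gst31 and -0.75 for the MADS-box gene MADS11. In all, 84 of 11748 probe sets departed, 25 above (29.8%) and 59 below. Of the 84, 11 were called above each parent and 8 below each with limma (adjusted p under 0.05). A mean between the parents' means was found for 28 of the 84. Without a named gene, Zm.12.1.S1_at at 1.85 and Zm.13679.1.A1_at at 1.62 lay highest, and Zm.13013.1.A1_at at -2.61 and Zm.5754.1.A1_at at -2.56 lowest. The transfer cell list lay below expectation with a median of -0.54 (adjusted p = 4.07e-05, and adjusted p = 0.607 with an estimated correlation). With limma, 0 of its 8 genes passed over all probe sets, 2 with the replicate block, 5 at an unadjusted p under 0.05 and 5 when adjusted over the list alone, and the called probe set of bap1-b is not the one the list holds. No other list passed (lowest adjusted p = 0.291). The share above was 19.2% after median centring, 38.0% after quantile normalization and 39.7% after trimmed mean scaling. The total was 167 with the replicate block, 184 after quantile normalization, 151 after median centring, 146 after trimmed mean scaling and 35 without the filter on dim probe sets. Equal weights of the parents gave 285. The total was 336 (86.3% above) with the log2-scale expectation, which is never above the linear one and so raises distances by construction. It was 36 without B73xMo17 replicate 3, 52 without B73xMo17 replicate 2 and 316 without Mo17 replicate 1, and 9 of 15 named calls were kept without B73xMo17 replicate 1 or replicate 3. With each array left out, zSSIIa, opr1, pdi4 and the 4 unnamed probe sets passed each time. The highest adjusted p of the others was 0.273 for obf3.2, 0.191 for an1, 0.293 for gst2 and 0.185 for MADS11 without B73xMo17 replicate 3, 0.0528 for GRF5, 0.243 for bap1-b and 0.125 for gst31 without B73xMo17 replicate 1, and 0.173 for hmt1 without B73xMo17 replicate 2. The call of gst2 was kept in 5 of 18 alternatives and that of bap1-b in 10 of 19.

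In Mo17xB73, the departures of named genes lay above expectation. The delta zein dzs18 had a signal of 9850 ± 1210 with parents at 13000 ± 340 and 417 ± 190. Its log2 distance was 1.1 (SE 0.216, adjusted p = 0.0214). A second, dimmer probe set of dzs18, with a signal of 127, gave 1.11. Neither is the probe set whose inbred signals are given above. In B73xMo17 the brighter one lay at 13900, with a distance of 0.66 that was not called (adjusted p = 0.306). Saturation of so bright a probe set was not tested. The tubulin gene tub5 reached 346 ± 40.4 with parents at 280 ± 9.23 and 159 ± 32.9, a distance of 0.77 (SE 0.155, adjusted p = 0.024), and a probe set of gst31 had 0.78. The call of gst31 was kept in 7 of 19 alternatives and that of the brighter probe set of dzs18 in 10 of 19. The adjusted p of gst31 was 0.321 without Mo17xB73 replicate 1. In all, 67 of 11748 probe sets departed, 62 above (92.5%) and 5 below. Of the 67, 17 were called above each parent and 2 below each with limma (adjusted p under 0.05). A mean between the parents' means was found for 21 of the 67. Without a named gene, Zm.12640.1.S1_at at 2.13 and Zm.15874.1.A1_at at 1.98 lay highest, and Zm.18395.1.S1_at at -1.70 and Zm.11651.1.A1_at at -1.25 lowest. The transfer cell list lay above expectation with a median of 0.76 (adjusted p = 7.73e-10). Its adjusted p was 0.0571 with an estimated correlation, and 0.039 with an estimated correlation and the replicate block. With limma, 0 of its 8 genes passed over all probe sets, 2 with the replicate block, 1 after quantile normalization, 7 at an unadjusted p under 0.05 and 7 when adjusted over the list alone. The zein list passed with 1 of 8 genes called, and 2 with the replicate block or when adjusted over the list alone (adjusted p = 0.0103, and adjusted p = 0.364 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0511). The aleurone list passed with 0 of 6 called with limma, 2 at an unadjusted p under 0.05 and 2 when adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.364 with an estimated correlation). The next lowest adjusted p of a list was 0.135. The share above depended on the scaling, at 51.5% after quantile normalization, 32.3% after median centring and 61.3% after trimmed mean scaling. The total was 161 with the replicate block, 103 after quantile normalization, 29 without the added constant, 24 without the filter and 103 with equal weights. The total was 512 (98.2% above) with the log2-scale expectation, which is never above the linear one and so raises distances by construction. It was 18 without Mo17xB73 replicate 3, 36 without Mo17xB73 replicate 1, 28 without B73 replicate 2 and 114 without Mo17 replicate 3, and 2 of 8 named calls were kept without Mo17xB73 replicate 3, where adjusted p rose to 0.159 and 0.213 for the probe sets of dzs18, 0.198 for tub5, 0.251 for gst31, 0.315 for Zm.11651.1.A1_at and 0.0683 for Zm.18395.1.S1_at. The brighter probe set of dzs18 was also not called after quantile normalization (adjusted p = 0.061), median centring (0.0971) and trimmed mean scaling (0.13).

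**Figure D3:**
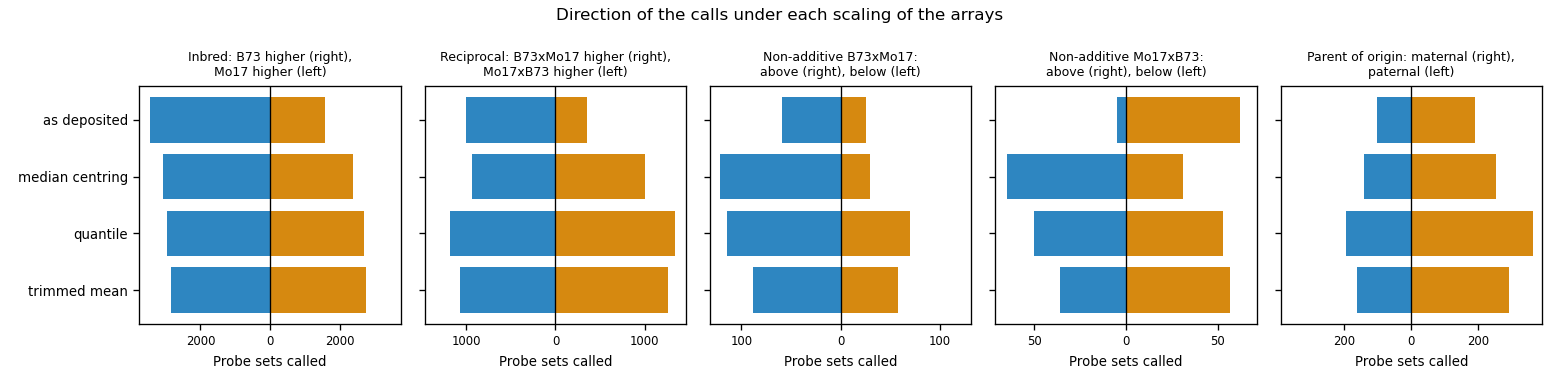
Number of probe sets called in each comparison (horizontal axes, each with its own range, drawn to the right and left of 0 by direction) with the arrays as deposited and after 3 scalings. The maternal share of the departures stays between 64.1% and 65.0%, whereas the B73 share of the inbred calls moves from 31.4% to 49.0% and the share above expectation in Mo17xB73 from 92.5% to 32.3%.

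Each hybrid was also set against each parent. B73xMo17 differed from its female parent B73 at 577 probe sets, 490 (84.9%) of them higher in the hybrid, and from its male parent Mo17 at 3422, 1271 (37.1%) higher. Mo17xB73 differed from its female parent Mo17 at 751, 680 (90.5%) higher, and from its male parent B73 at 3125, 2435 (77.9%) higher. The median shift was -0.15 for B73xMo17 against Mo17 and 0.21 for Mo17xB73 against B73. After quantile normalization the higher shares were 63.1%, 47.5%, 65.9% and 46.9% in the same order, after median centring 55.3%, 35.3%, 49.0% and 41.1%, and after trimmed mean scaling 67.9%, 53.0%, 71.0% and 49.9%. Under the dose of 2 to 1, a hybrid can lie at most 1.5-fold below its female parent but any distance above it. Simulated changes of 1.5-fold were recovered at 28.4% for B73xMo17 against B73 and 19.4% for Mo17xB73 against Mo17. Additive hybrids would thus also give mostly higher calls against the female parent, so these shares show no general rise. The transfer cell marker meg2 lay nearer its female parent in each hybrid, with 949 ± 250 in B73xMo17 beside 573 ± 81.5 in B73 and 3880 ± 339 in Mo17xB73 beside 3020 ± 994 in Mo17. Without Mo17 replicate 1, the dimmest array, the count for B73xMo17 against Mo17 was 5723. That for Mo17xB73 against Mo17 was 1558, of which 698 (44.8%) were higher and 860 lower, so that the majority turned. Without Mo17 replicate 2 the count for B73xMo17 against Mo17 was 2265. Without Mo17 replicate 3 it was 2484 with 51.5% higher. After scaling, the count against the female parent was 1026 (quantile), 868 (median) and 976 (trimmed mean) for B73xMo17 and 1214, 1395 and 1250 for Mo17xB73, which also fell to 480 with the dimmer 50% of probe sets left out.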

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

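The 6 tests of technical explanations below were chosen after the results were seen, and the bound of the test on the share of transfer cells was set after its value was known, whereas the counts of regrouped arrays were planned before the data were examined.

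Each named non-additive probe set was tested for a difference between the hybrids, B73xMo17 minus Mo17xB73, which equals the unsigned departure from dose. Of 23 tested, 22 differed, 15 lower and 7 higher in B73xMo17, with adjusted p of 0.0324 or less over the 23. They had been picked for a departure in 1 hybrid, which favours a difference. Lower in B73xMo17 were zSSIIa at -2.36, bap1-b at -2.06, hmt1 at -1.83, opr1 at -1.60, gst2 at -1.25, pdi4 at -0.99, gst31 at -0.83 and, for a second probe set, -0.60, dzs18 at -0.60, MADS11 at -0.55 and tub5 at -0.52. Unnamed probe sets on this side were Zm.5754.1.A1_at at -3.38, Zm.13013.1.A1_at at -2.72, Zm.12640.1.S1_at at -1.95 and Zm.15874.1.A1_at at -1.37. Higher in B73xMo17 were GRF5 at 1.57, obf3.2 at 0.99 and an1 at 0.93, and Zm.18395.1.S1_at at 1.99, Zm.11651.1.A1_at at 1.64, Zm.12.1.S1_at at 1.37 and Zm.13679.1.A1_at at 0.91. The brighter probe set of dzs18 did not pass, at -0.43 (adjusted p = 0.0664).

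More of the inbred calls were higher in Mo17 (68.6%) than in B73. A difference in array brightness may account for this, since 52.4% were higher in Mo17 after quantile normalization. Probes that match Mo17 transcripts better remain open: among 242 calls of at least 8-fold, 47.9% were higher in Mo17 (exact 95% interval 41.5 to 54.4), which neither needs nor excludes such probes. The interval takes the probe sets as independent, although they share the same arrays, so it does not measure the spread between replicates. A true difference in total transcript between the lines, which quantile normalization would remove as well, stays open and untested.

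Departures toward the female parent outnumbered those toward the male parent at 65.0%. A difference in array brightness was argued against by a share of 64.9% after quantile normalization. The scale on which the parents' doses add up matters for the excess, since the female share was 47% with an expectation on the log2 scale. That expectation is the larger at every inbred difference, so it moves each departure toward the male parent by construction. The excess thus depends on the scale, but this test cannot decide whether the scale accounts for it. Of the 191 female-ward departures, 151 were at probe sets higher in Mo17, as were 27 of the 103 male-ward ones and 68.6% of the 5013 tested, while after quantile normalization 194 female-ward departures were at those higher in Mo17 and 169 at those higher in B73. Imprinting, which the comparison was made to find, stays open beside these. Expression from the female parent's alleles alone would give a weight of 1, whereas the median weight among the 191 was 1.13. Those probe sets were picked for departing, which favours extreme weights, so the median does not decide this.

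Transfer cell markers were higher with Mo17 as the female parent, with a median reciprocal difference of -1.91. A difference in array brightness was argued against by a median of -1.76 after quantile normalization. A different share of transfer cells in the dissected tissue cannot be told apart from expression within those cells: the markers' departures from dose ran from -1.57 to -0.51, and their SD was 1.51 times their root mean square standard error, between the bounds set for that test. The bounds took the markers' errors as independent, but their residuals were correlated (estimated at 0.629). Equal departures would then give a lower ratio than the bounds assume, so this test decides nothing. All 8 markers had a higher mean in Mo17xB73 than in Mo17, and the embryo markers glb1 and ole1 were also higher in Mo17xB73. A parent-of-origin effect on these genes may exist beside this, as a hypothesis found and tested on the same data.

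Regrouping the arrays of each comparison showed how often other groupings gave as many calls. In each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, reached its count for B73 against Mo17 (5013, highest other 0), for the reciprocal hybrids (1353, highest other 0), for B73xMo17 against B73 (577, highest other 2) and against Mo17 (3422, highest other 1), and for Mo17xB73 against Mo17 (751, highest other 0) and against B73 (3125, highest other 0). Of these 10 splits, 4 divide all 3 crossing dates as the real one does, and the highest count among the other such splits was 1, for B73xMo17 against Mo17. Every split other than the real one puts 2 arrays of 1 genotype with 1 array of the other. This shrinks the genotype difference and moves it into the spread. Low counts in those splits were thus favoured in advance and decide nothing about chance. For departures from dose, 2 of 100 groupings gave as many as 294, the highest other being 389. Of the 99 other groupings, 94 left no probe set with an inbred difference to test, so this count decides nothing about chance. For non-additive expression, 5 of 100 groupings gave as many as 84 in B73xMo17 (highest other 4669) and 7 of 100 as many as 67 in Mo17xB73 (highest other 4260). These groupings mix inbred arrays with hybrid arrays and carry the inbred difference, so they decide nothing about chance either. Counts that far above the real ones point to a structure of the samples. The groupings into 3 or 4 genotypes did not keep the crossing dates together.

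The non-additive results of both hybrids share the same parent arrays. Across probe sets, which are not independent, they correlated at 0.0156, against 0.309 (0.29 to 0.328) in 100 simulations of purely additive hybrids with these parents, where the covariance was 0.0109 against 0.000893 measured, a difference of -0.01. The simulations drew independent noise for each probe set and array. They held neither the deviations shared by arrays of the same crossing date nor the unequal brightness of the arrays. Both can change this covariance, so the gap decides nothing about additivity. The 3 arrays per parent were too few to be divided between the hybrids. Of the calls, 3 were above and 0 below expectation in both hybrids with limma, where these simulations gave 0 and 0.01 on average and independent lists give 0.132 and 0.0251, and 2 were opposite, against 0 in the simulations and 0.322 with independent lists. These 5 probe sets, named after their values were seen, were Zm.12634.1.A1_at (1.1 in B73xMo17 and 1.54 in Mo17xB73), Zm.14798.1.S1_x_at (1.46 and 0.99), Zm.16958.4.S1_at (1.31 and 1.07), Zm.10267.1.A1_at (-0.999 and 1.25) and Zm.18422.1.S1_at (-0.93 and 0.90).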

How the results depend on the processing

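Scaling to the trimmed mean and the alternatives for positions and weights were chosen after the data were seen, and the other alternatives before. Among alternative values of the counts, positions and weights, 184 stayed within 1.5 times the count or within the spread of replicates and 46 moved. The counts include those of named calls kept and of list tests passed. With an array left out or only the groups compared, named calls kept were set against the named calls tested in that setting. Among alternative values of single named genes, 2639 kept their direction and their side of the threshold, 253 lost the call, 23 gained it and 10 changed sign. The number of calls between the inbreds and in Mo17xB73 against B73, the positions and the weight stayed within those limits in every setting run. The unequal brightness of the arrays limits these results, as do signals under the added constant of 10.6. After quantile normalization the counts were 2514 for the reciprocal difference, 184 and 103 for non-additive expression in B73xMo17 and Mo17xB73, 559 for departures from dose, 1026 for B73xMo17 against B73 and 1214 for Mo17xB73 against Mo17. After median centring they were 151 for non-additive B73xMo17, 868 for B73xMo17 against B73 and 1395 for Mo17xB73 against Mo17. After trimmed mean scaling they were 2326 for the reciprocal difference, 146 for non-additive B73xMo17, 454 for departures, 976 for B73xMo17 against B73 and 1250 for Mo17xB73 against Mo17. The cause was not tested. Of the calls with the deposited values, 4498 of 5013, 1258 of 1353, 78 of 84, 41 of 67 and 260 of 294 were also made after quantile normalization, for the inbred, reciprocal, non-additive and departure tests in that order, all with the same sign. The replicate block gave 2075 for the reciprocal difference, 167 and 161 for non-additive expression and 466 for departures, moved no other count over 1.5 times and changed no called named gene. The reciprocal count was 2137 with only the groups compared and 2117 at an adjusted p under 0.10, and non-additive Mo17xB73 had 112 at that threshold, which is looser by construction. Without the filter, non-additive counts were 35 and 24, with more probe sets tested. Without the added constant, non-additive Mo17xB73 had 29, and with the dimmer 50% left out Mo17xB73 against Mo17 had 480. The cause was not tested. An expectation on the log2 scale gave 336 and 512 non-additive calls. Equal weights of the parents gave 285 and 103, as another expectation is tested in both cases. The log2-scale expectation is never above the linear one, so it raises distances by construction. Gene list tests passed 10 times with the preset correlation and 2 times with an estimated one, which widens the variance of each list. With 1 array left out, counts ran from 732 (without Mo17xB73 replicate 3) to 1125 for the reciprocal difference, from 36 (without B73xMo17 replicate 3) to 316 (without Mo17 replicate 1) for non-additive B73xMo17, from 18 (without Mo17xB73 replicate 3) to 114 (without Mo17 replicate 3) for non-additive Mo17xB73, from 140 (without B73xMo17 replicate 3) to 397 for departures, from 2265 (without Mo17 replicate 2) to 5723 (without Mo17 replicate 1) for B73xMo17 against Mo17, and from 566 to 1558 (without Mo17 replicate 1) for Mo17xB73 against Mo17. The cause was not tested. The 10 changes of sign were in 2 photosystem genes that were not called. Non-additivity of psah1 in Mo17xB73, 0.11, was -0.13 after quantile normalization, -0.0776 after median centring and -0.122 to 0.336 with 1 array left out, and its departure from dose, 0.10, was -0.124 to 0.335 with 1 array left out. That of lhcb6, 0.05, was -0.0959 after quantile normalization, -0.115 after median centring, -0.0117 after trimmed mean scaling and -0.0867 to 0.278 with 1 array left out. The cause was not tested.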

Other observations

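Zein transcripts other than those of dzs18 and z1C1_12 differed little in mean signal between the 4 genotypes, among them the gamma zein gz27 (8960 ± 455 in B73, 8860 ± 201 in Mo17, 9330 ± 506 in B73xMo17 and 9190 ± 84.3 in Mo17xB73) and z1D_2 (14200 ± 518, 13900 ± 960, 14900 ± 863 and 14900 ± 664). None of these was called between the inbreds or between the hybrids with the arrays as deposited, although 4 of the 8 zeins tested, against 2 as deposited, were higher in B73 after quantile normalization. Saturation of such bright probe sets was not tested. Genes chosen here after their values were seen include fie1, a Polycomb gene described as imprinted in the literature, at 1110 ± 19.8 in B73, 896 ± 234 in Mo17, 1050 ± 203 in B73xMo17 and 735 ± 57.5 in Mo17xB73. Its inbred difference was not called (adjusted p = 0.168), so its departure from dose was not tested, and its reciprocal difference of 0.50 was not called either (adjusted p = 0.106).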
